A study of Mus musculus with 10 samples.

How the data were processed

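The libraries were made from RNA of the whole brain of 10 Swiss Webster pups, 5 with hypoxic-ischemic injury and no treatment and 5 with the injury and allopregnanolone, per the labels. Per the labels' protocols, RNA was extracted with the RNeasy Mini Plus kit, and 1 µg of total RNA went into libraries made with the NEBNext Ultra II Directional kit. The submitters' processing notes name Partek and the mm10 genome. The aligner, the program that assigned reads to genes, the annotation and the strand setting of the counting are not given in the sources used here, so the origin of reads is uncertain for genes that overlap others on the opposite strand, such as Pmch and Sox4.

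The values used are the gene table as deposited by the authors, which holds estimated counts (expected counts) for 55471 Ensembl gene identifiers in 10 libraries. The table's name calls the values normalized, but they look like counts before normalization: 86.8% to 87.6% of the values above 0 were whole numbers and the library totals ranged from 18656840 to 34270720. They were rounded to whole numbers and analysed as counts, the branch that the plan held for that case in place of limma on normalized values. Gene names, types and coordinates came from GENCODE M21 (GRCm38), in which 55230 identifiers were found and 241 were not. No column was left out.

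Genes were kept if at least 5 of the 10 libraries had 10 or more counts, which left 17101 genes and 99.9% of the counts of each library (3 digits). Counts were scaled by TMM (factors 0.953 to 1.04) and compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with no covariate, an adjusted p under 0.05 (Benjamini-Hochberg over all genes kept) as threshold and a two-sided test. Log2 fold changes are treated minus untreated, and their standard errors are the fold change divided by the square root of the F statistic. CPM values are scaled by TMM and given as mean ± SD over the 5 libraries of a group. Mice were treated as separate animals.

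Of 49 gene lists written from textbook knowledge before the data were examined, 43 with at least 5 genes kept were tested with camera of limma 3.58.1, on log2 CPM with a prior count of 1. The preset correlation between genes was 0.01, and p values were adjusted over the lists. The same lists were tested with an estimated correlation and with fry. The mean log2 CPM of each list per library was compared by an exact permutation test over all 252 assignments, whose smallest p is 0.00794. Neutrophils, lymphocytes, pituitary and hindbrain with spinal cord had 1, 2, 1 and 0 genes kept and were not tested, and Y-linked and X inactivation genes served to read the sex of the pups. The separation of the groups was tested over the 126 splits into 5 and 5. A midbrain list and lists of genes that fall or rise after birth were written after the gene test. Slopes of 1 list mean on another within groups came from a linear model with the group as a term, on the scale of the covariates, which are means of log2(CPM + 1). The difference between the groups in the mean of the inflammatory and complement lists is on the same scale, with a pooled t interval over libraries.

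Named genes follow a rule set before the data were examined. They are the 12 higher and the 12 lower genes with the largest absolute log2 fold change past the threshold, leaving out pseudogenes and unnamed Gm and Rik genes, a panel of 18 genes, up to 4 members with the smallest p of each list described and the 5 most abundant genes. Some genes that the rule names are not reported here. Of the 12 lower genes Chtf8 (log2 fold change -2.33) is not discussed, since a second identifier of the same name covers 100% of its exons.

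Between libraries of 1 group, log2 CPM correlated at 0.980 to 0.987, and the spread between libraries exceeded counting noise, with a chi-square per degree of freedom of 5.45 to 19.8. On simulated data with 200 changed genes the test found 64% of 1.5-fold and 80% of 2-fold changes, and 6.49% of the genes called were unchanged ones.

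Alternatives to the gene test numbered 31. They were limma-trend with prior counts of 0.1, 1 and 4, no count filter, a filter of 100 counts, median-of-ratios, upper-quartile and quantile scaling, library totals alone, library weights, robust empirical Bayes, DESeq2 1.42.0, covariates (Y-linked, red blood cell, choroid plexus, midbrain and myelin means), each library left out in turn, the 3 libraries of another name prefix left out, untreated library 5 and treated library 6 left out together, a trend on GC content and length removed, and thinning of all libraries to 18656827 counts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.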

Results

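Whole-brain RNA was sequenced from 10 Swiss Webster mouse pups that the labels give as neonatal day 5, all with a hypoxic-ischemic brain injury, in which the brain is deprived of blood flow and oxygen. Whether that day is the day of injury or of collection is not settled here. In 5 pups the injury was left untreated, and 5 further pups received allopregnanolone, a steroid made from progesterone that acts on GABA-A receptors, the chloride channels opened by the transmitter GABA. Each pup gave 1 library, and the pups carry their own numbers, 1 to 5 in the untreated group and 6 to 10 in the treated group. Estimated counts per library summed to between 18656840 and 34270720, and treated library 6 was the deepest. Mitochondrial transcripts, led by mt-Co1, mt-Cytb and mt-Nd1, took 7.98% to 9.76% of the counts of a library. Dose, litter and the interval between injury and collection were not used here.

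The comparison asks how the transcriptome of the injured neonatal brain differs when allopregnanolone has been given. With allopregnanolone 18 of 18 myelin genes, 11 of 16 glucocorticoid-responsive genes and 7 of 13 astrocyte genes rose, and 9 of 24 proliferation genes, 6 of 14 immature neuron genes, 4 of 16 inflammatory cytokine and chemokine genes and 3 of 12 complement genes fell. These lists were among 15 of 43 that passed camera with a preset correlation, and none passed with an estimated correlation (smallest adjusted p = 0.0898, with 3 lists at an unadjusted p under 0.05). Several of the counts were much smaller with 1 library left out or with a covariate, as given below. Of 17101 genes tested, 1926 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 1131 of them higher and 795 lower with allopregnanolone. A change of over 2-fold was reached by 108 of the higher and 72 of the lower genes. The counts of higher and lower genes depend on the scaling, since with library totals alone 783 genes were higher and 1451 lower, with a median shift of -0.06 over all genes on the log2 scale. Among the 1926 genes, 1295 had no overlap between the 5 treated and the 5 untreated libraries. Over all genes tested this was so for 9.64%, against 0.794% by chance.

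Genes of oligodendrocytes, the cells that wrap axons in myelin, were higher in the treated brains. All 18 members of the oligodendrocyte and myelin list rose, with a median fold of 2.24. Mbp, which encodes myelin basic protein (ENSMUSG00000041607, chromosome 18, 82475146 to 82585637 on GRCm38), averaged 1540 ± 478 CPM (SD, n = 5) in untreated and 3619 ± 466 CPM (SD, n = 5) in treated libraries. Its log2 fold change was 1.23 (SE 0.18, adjusted p = 0.00147, edgeR), and all 5 treated libraries lay above every untreated library. Mal, a proteolipid of compact myelin (chromosome 2, 127633226 to 127656695), rose 2.89-fold from 17.0 ± 6.20 to 49.1 ± 4.59 CPM (SD, n = 5 each). Opalin and Ermn, both specific to mature oligodendrocytes, rose 2.71-fold and 2.34-fold, and the tetraspanin Tspan2 rose 1.78-fold. Of 11 oligodendrocyte precursor genes, 6 rose and 5 did not pass, 7 rising when adjusted over the list alone. Among them were Gpr17, a receptor of differentiating precursors (1.41-fold), the transcription factors Olig1 (1.40-fold) and Sox8, and the sialidase Neu4. The camera test with a preset correlation gave adjusted p = 4.94e-16 for the myelin list and 0.00328 for the precursors. With an estimated correlation both had an adjusted p = 0.589, the estimated correlation between genes being 0.85 and 0.36.

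**Figure D1:**
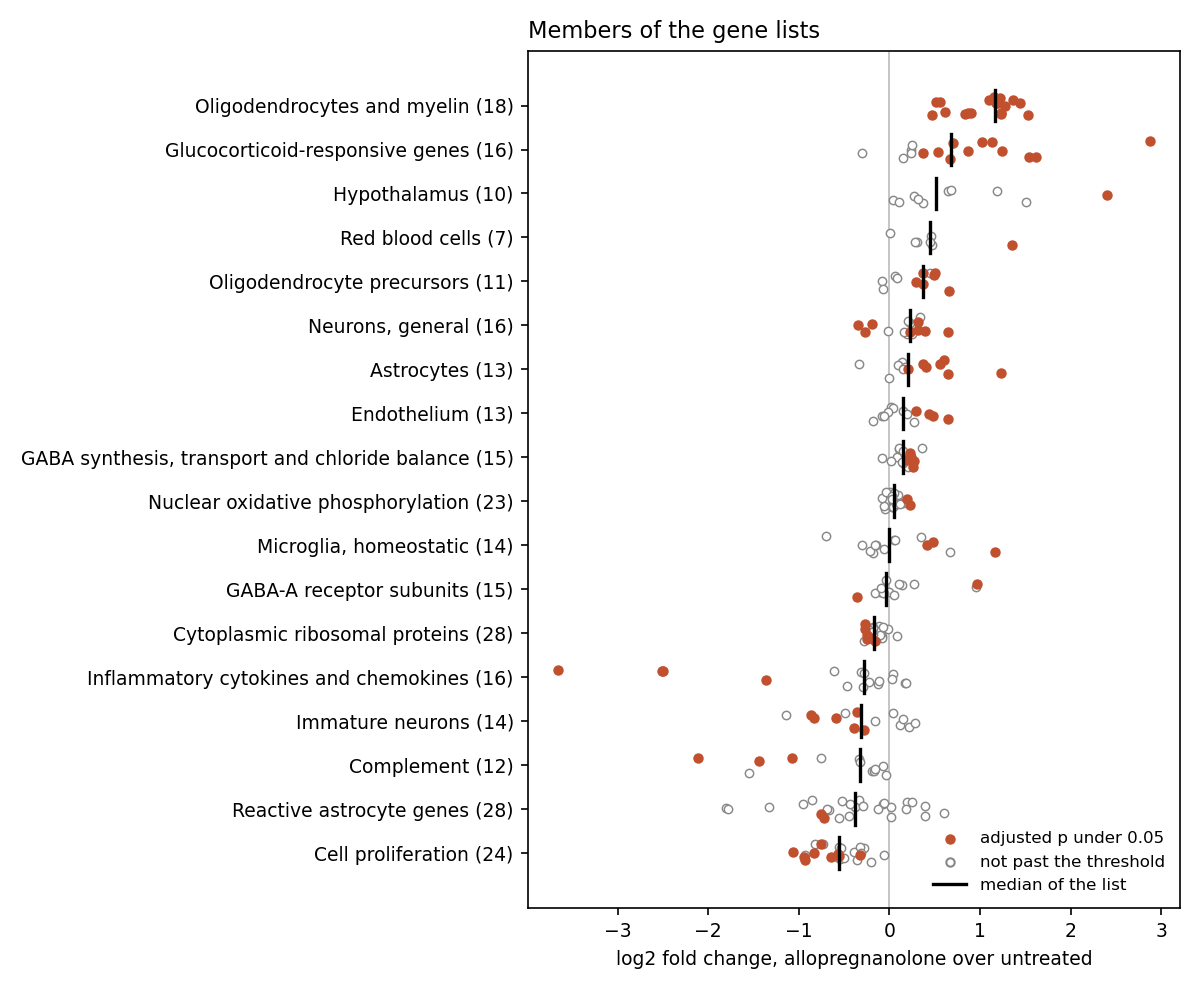
Log2 fold change, allopregnanolone over untreated, of each tested member (point) of the 15 gene lists past the camera threshold and of 3 further lists, with the number of tested members in brackets. Filled points passed an adjusted p of 0.05, open points did not, and black lines are list medians; all 18 myelin genes lie to the right of 0 and all 24 proliferation genes to the left.

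Glucocorticoid-responsive genes were higher as well, 11 of 16 past the threshold and 14 when adjusted over the list alone, with none lower. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein (ENSMUSG00000031431, chromosome X, 140539528 to 140600659), rose 2.19-fold from 27.5 ± 2.98 to 60.3 ± 10.9 CPM (SD, n = 5 each, adjusted p = 0.000193, edgeR). Mertk, a receptor for the engulfment of dying cells, rose 2.37-fold, Hif3a 2.03-fold and Sult1a1, a sulfotransferase, 2.91-fold. Plin4, which coats lipid droplets, rose 7.35-fold from a low level of 0.191 ± 0.194 to 1.42 ± 0.565 CPM (SD, n = 5 each). Camera gave the list an adjusted p = 1.82e-08, and adjusted p = 0.589 with an estimated correlation.

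Astrocyte genes rose in 7 of 13 cases, with none lower over all genes tested, and in 9 cases with 1 lower when adjusted over the list alone. Gjb6, the gap junction protein connexin 30 (ENSMUSG00000040055, chromosome 14, 57123303 to 57133611), had the smallest p of all named genes. It rose 2.34-fold from 18.0 ± 2.17 to 42.1 ± 3.81 CPM (SD, n = 5 each), with an adjusted p = 2.86e-05 in edgeR's test. The growth factor receptor Fgfr3 rose 1.51-fold, the glycolytic enzyme Aldoc 1.57-fold and the calcium-binding protein S100b 1.47-fold. Camera gave the astrocyte list an adjusted p = 8.56e-07, and adjusted p = 0.0898 with an estimated correlation. Reactive astrocyte genes did not pass as a list (adjusted p = 0.0598, camera). Within it S100a10 and B3gnt5 fell, and Gfap, the intermediate filament of astrocytes, stood at 385 ± 200 CPM untreated and 213 ± 43.7 CPM treated (SD, n = 5 each, adjusted p = 0.0771, edgeR). Of 13 endothelial genes 4 rose, 6 when adjusted over the list alone, among them the lipid transporter Mfsd2a (1.56-fold), Ly6c1, the efflux pump Abcb1a and the receptor Flt1 (camera adjusted p = 0.0109, and adjusted p = 0.589 with an estimated correlation). Slc2a1, the glucose transporter of the blood-brain barrier, rose 1.88-fold from 49.2 ± 1.37 to 92.6 ± 11.3 CPM (SD, n = 5 each, adjusted p = 8.29e-05, edgeR).

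Several of the 12 named genes with the largest falls are known from microglia and other myeloid cells, a grouping made after the values were seen. Ccl3, a chemokine (ENSMUSG00000000982, chromosome 11, 83647844 to 83649355), averaged 3.81 ± 3.04 CPM untreated and 0.281 ± 0.135 CPM treated (SD, n = 5 each), 12.6-fold lower (adjusted p = 0.00492, edgeR). Cd52, a surface glycoprotein of leukocytes, was 16.1-fold lower and Clec7a, a receptor of activated microglia, 8.98-fold lower. The cytokine Il1a was 5.64-fold, the receptor Tlr2 5.69-fold, Slamf8 7.12-fold and Gpr84 6.20-fold lower, and Cybb, Slamf9, Adgrg5, Cxcl16 and Clec5a also fell. The last 2 missed the threshold in 18 and 21 of 30 alternative analyses, Cybb in 12, Adgrg5 in 10 and the complement gene C4b in 20 of 31. Untreated library 5 was below every treated library for Cxcl16, at 0.312 against 0.508 to 0.944 CPM, and for C4b, at 6.72 against 8.67 to 13.2 CPM. Of 16 inflammatory cytokine and chemokine genes 4 fell, the same number when adjusted over the list alone, and 12 did not pass. Of 12 complement genes 3 fell, namely C3ar1, Itgb2 and C4b, a close copy of C4a, and 6 when adjusted over the list alone. Camera gave adjusted p = 0.0155 and 0.00983 for these lists, and adjusted p = 0.589 and 0.611 with an estimated correlation. Il1b and Tnf were below the count minimum, at 0.434 ± 0.229 and 0.362 ± 0.272 CPM untreated and 0.0790 ± 0.0730 and 0.0496 ± 0.0512 CPM treated (SD, n = 5 each). Untreated library 5 was near the treated level, with 0.312 CPM of Ccl3 and 0.801 CPM of Cd52, while untreated library 1 was the highest for both, at 7.93 and 20.8 CPM. For Tlr2 untreated library 1 was at 12.5 CPM and the other untreated libraries at 1.02 to 4.09 CPM, so the size of these folds leans on untreated library 1. Homeostatic microglia genes did not pass as a list (adjusted p = 0.644, camera; median log2 fold change -0.0040, mean 0.10), and 3 of 14 rose, namely Tmem119 (1.39-fold), Selplg and Slc2a5. Of 18 activated microglia genes Clec7a and Tyrobp fell and Apoe, a lipid carrier that astrocytes also make, rose 1.22-fold, with camera adjusted p = 0.140 for the list.

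**Figure D2:**
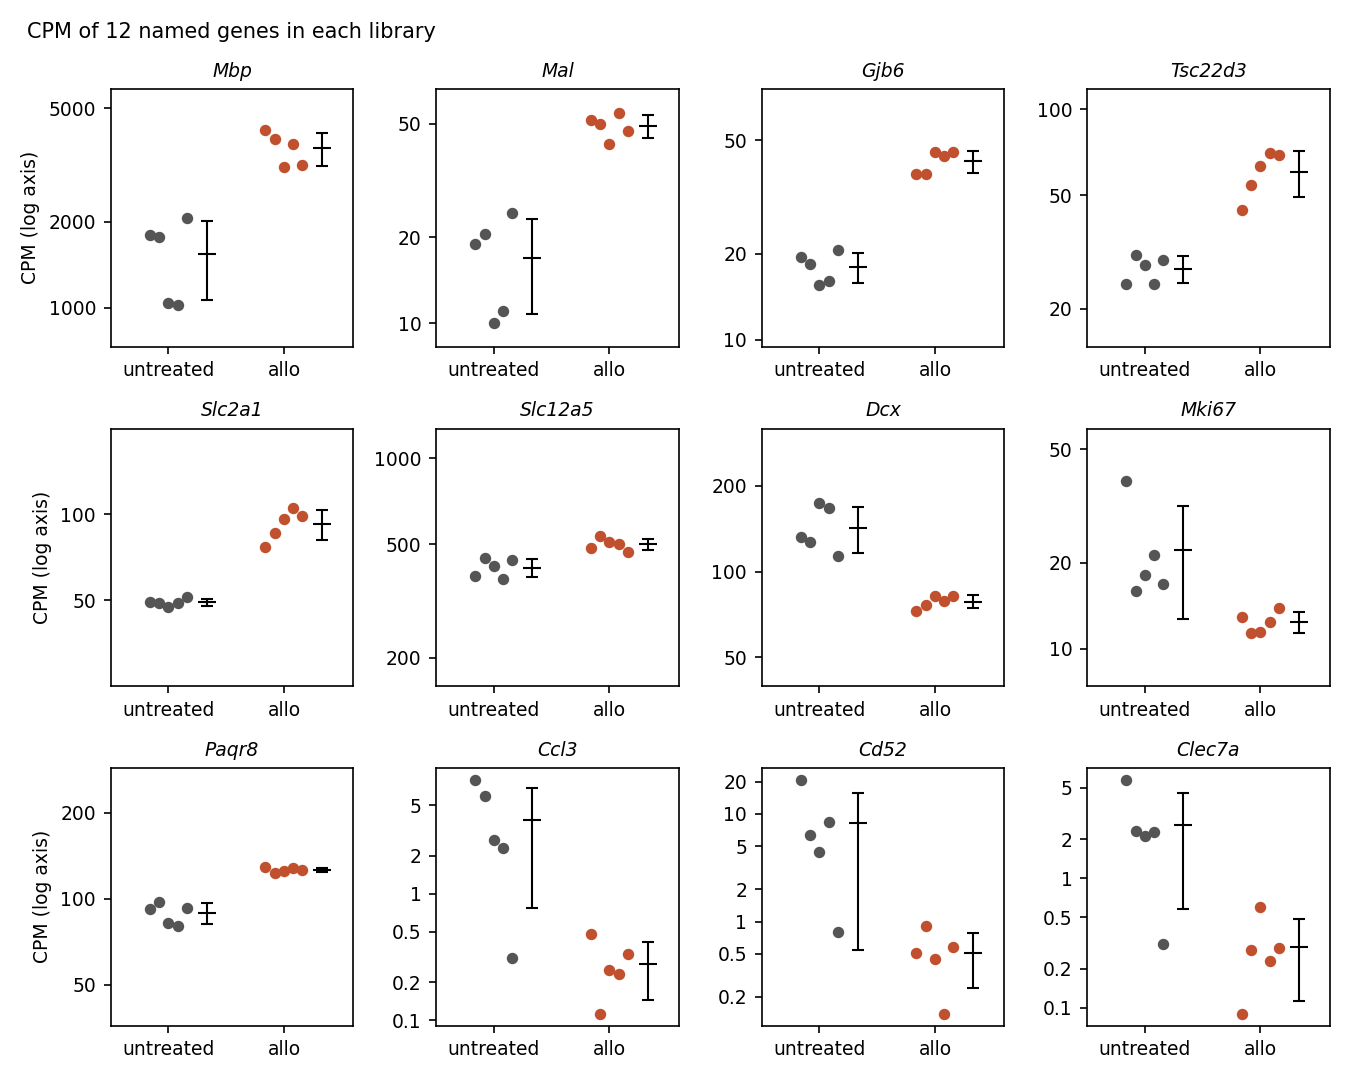
CPM on log axes of 12 named genes in each of the 5 untreated and 5 allopregnanolone libraries (points, in order of pup number), with the mean and SD of each group beside them. For Mbp, Mal, Gjb6, Tsc22d3, Slc2a1, Slc12a5, Dcx, Mki67 and Paqr8 the groups do not overlap, and untreated library 5, the last grey point, lies close to the treated libraries for Ccl3, Cd52 and Clec7a.

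Genes of cell division and of young neurons were lower. Of 24 proliferation genes 9 fell and none rose, and 16 fell when adjusted over the list alone. Mki67, the marker of cycling cells, went from 22.1 ± 9.40 to 12.4 ± 1.08 CPM (SD, n = 5 each, 1.78-fold lower, adjusted p = 0.0216, edgeR). Top2a, Bub1b and Pcna were 1.68-fold, 2.09-fold and 1.25-fold lower. Of 14 immature neuron genes 6 fell, and 1 rose and 6 fell when adjusted over the list alone. Dcx, which encodes the microtubule protein doublecortin of migrating neurons (ENSMUSG00000031285, chromosome X, 143855842 to 143933311), was 1.82-fold lower, at 143 ± 26.1 CPM untreated and 78.4 ± 4.16 CPM treated (SD, n = 5 each, adjusted p = 0.000434, edgeR). Neurod6 was 1.51-fold, Sox4 1.31-fold and Elavl2 1.21-fold lower. Among 16 general neuron genes 5 rose and 3 fell, and 11 rose and 3 fell when adjusted over the list alone. The early tubulin Tubb3 and the growth cone protein Stmn2 fell, and the kinase Camk2a and the enolase Eno2 of mature neurons rose. Of 28 ribosomal protein genes 6 fell, 14 when adjusted over the list alone, by small amounts such as 1.20-fold for Rpl10a, and the median fold of the list was 0.887. Camera gave adjusted p = 2.29e-08 for proliferation, 6.39e-07 for ribosomal proteins, 0.020 for immature neurons and 0.0462 for neurons. With an estimated correlation these were adjusted p = 0.589 for the former 3 lists and 0.695 for neurons. Pvalb, the calcium buffer of fast-spiking interneurons, rose 2.37-fold while Dlx1 and Dlx6os1, active in young interneurons, fell, and the interneuron list did not pass (adjusted p = 0.418, camera).

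GABA-A receptor subunit genes, which encode the channels that allopregnanolone binds, did not pass as a list (adjusted p = 0.762, camera; median log2 fold change -0.04, mean 0.10; 1 of 15 higher and 1 lower, the same when adjusted over the list alone). Gabra5 fell from 121 ± 3.32 to 94.1 ± 13.2 CPM (SD, n = 5 each, adjusted p = 0.0128, edgeR), and Gabre rose 1.96-fold. Gabre missed the threshold in 13 of 31 alternative analyses. Log2 fold changes were -0.11 (SE 0.07) for Gabra2, 0.00 (SE 0.09) for Gabra4 and 0.11 (SE 0.15) for Gabrd, none past the threshold. Genes of GABA synthesis, transport and chloride balance rose in 5 of 15 cases, 8 when adjusted over the list alone (camera adjusted p = 0.000651, and adjusted p = 0.589 with an estimated correlation). Both chloride cotransporters rose by similar amounts. Slc12a5, which exports chloride, went from 413 ± 30.7 to 499 ± 23.8 CPM (SD, n = 5 each, 1.21-fold, adjusted p = 0.0111, edgeR), and Slc12a2, which imports it, rose 1.20-fold (adjusted p = 0.00884, edgeR). The GABA-degrading enzyme Abat rose 1.17-fold, but missed the threshold in 14 of 31 alternative analyses and turned to the opposite direction in 1. Glutamate receptor genes went both ways, 3 higher and 2 lower of 22 (5 and 3 when adjusted over the list alone; median log2 fold change -0.02, mean 0.04; camera adjusted p = 0.879). The NMDA receptor subunit Grin2c rose 1.92-fold, while Grin3a and the metabotropic receptor Grm5 fell. Of the progestin receptor genes Paqr8, a membrane progestin receptor, rose 1.42-fold from 88.9 ± 7.44 to 126 ± 2.36 CPM (SD, n = 5 each, adjusted p = 0.000313, edgeR), with camera adjusted p = 0.0657 for the list. Of 12 neurosteroid synthesis genes only Por passed, rising 1.17-fold, and Tspo, the mitochondrial translocator protein, stood at 1.20 ± 0.629 CPM untreated and 0.692 ± 0.292 CPM treated (SD, n = 5 each, adjusted p = 0.211, edgeR).

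The lists of injury responses did not pass as wholes by camera, though the oxidative stress list passed fry (adjusted p = 0.0380). Of 27 apoptosis genes 1 rose and 3 fell, the same when adjusted over the list alone. The survival gene Bcl2l1 rose from 96.0 ± 5.21 to 112 ± 2.48 CPM (SD, n = 5 each, 1.17-fold, adjusted p = 0.00933, edgeR) and the death gene Bbc3 fell (camera adjusted p = 0.207 for the list). Bbc3 missed the threshold in 17 of 31 alternative analyses and Bcl2l1 in 3. Of 24 hypoxia-inducible genes Slc2a1 and Aldoa rose and P4ha1 fell (adjusted p = 0.587, camera), the last missing the threshold in 16 of 31 alternative analyses. Of 24 oxidative stress genes 6 rose and 1 fell, the metallothionein Mt1 rising 1.80-fold and Gsta4 1.38-fold (adjusted p = 0.0598, camera). Immediate early genes went both ways, with Jun and Klf4 higher and Fosl2 and Nr4a3 lower (adjusted p = 0.418, camera). Hmox1, Bdnf and the neuronal nuclear marker Rbfox3 did not pass, with log2 fold changes of -0.18 (SE 0.14), -0.28 (SE 0.13) and 0.22 (SE 0.08), and neither did the microglial marker Aif1 at -0.70 (SE 0.25).

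Some genes known from brain regions or from blood also differed between the groups. Of the 12 named genes with the largest rises, 6 are known from the midbrain or from dopamine neurons, namely the transcription factors En1 (16.9-fold), Pax5, Pax7 and Gata3, the receptor subunit Chrna6 and the dopamine transporter Slc6a3 (10.4-fold, adjusted p = 0.0205, edgeR). Slc6a3 averaged 17.6 ± 14.7 CPM treated and 1.72 ± 2.53 CPM untreated (SD, n = 5 each), and it was 36.4, 23.2 and 23.2 CPM in treated libraries 6, 7 and 9 but 3.03 and 2.35 CPM in treated libraries 8 and 10. Untreated library 2, at 6.25 CPM, lay above treated libraries 8 and 10 and set the untreated mean, with the other untreated libraries at 0.445 to 0.739 CPM. An 18-gene midbrain list, written after the named genes had been seen and so no independent evidence, summed to 26.6 to 50.7 CPM in untreated and to 37.6 to 176 CPM in treated libraries. The myelin list summed to 2401 to 4479 CPM in untreated and to 6680 to 9040 CPM in treated libraries, and treated libraries 8 and 10, with midbrain sums of 37.6 and 38.2 CPM, had myelin sums of 6680 and 6814 CPM. The other 6 of the 12 genes with the largest rises were Plin4, Cnpy1, Alox12b, Tmem52, Barhl1 and Pmch. Barhl1 (7.49-fold) had the largest rise on the cerebellum list. Pmch is the hypothalamic melanin-concentrating hormone gene (5.27-fold), part of whose exons lie opposite those of Parpbp. Region markers among the 12 genes are thus not limited to the 6 known from the midbrain or from dopamine neurons. The hypothalamus list had camera adjusted p = 0.0392 with 1 of 10 genes past the threshold, and the red blood cell list 0.0451 with 1 of 7, Slc4a1. These were adjusted p = 0.629 and 0.611 with an estimated correlation. Red blood cell genes summed to 600 to 1469 CPM untreated and to 977 to 1575 CPM treated. Nuclear oxidative phosphorylation genes, 2 of 23 higher (Cox4i1 and Uqcrc1), had camera adjusted p = 0.0487 and adjusted p = 0.695 with an estimated correlation, and their median of 0.05 on the log2 scale became -0.01 with library totals alone. Slc4a1 missed the threshold in 16 and Chrna6 in 14 of 30 alternative analyses. Uqcrc1 missed it in 15 of 31 and turned to the opposite direction in 1.

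**Figure D3:**
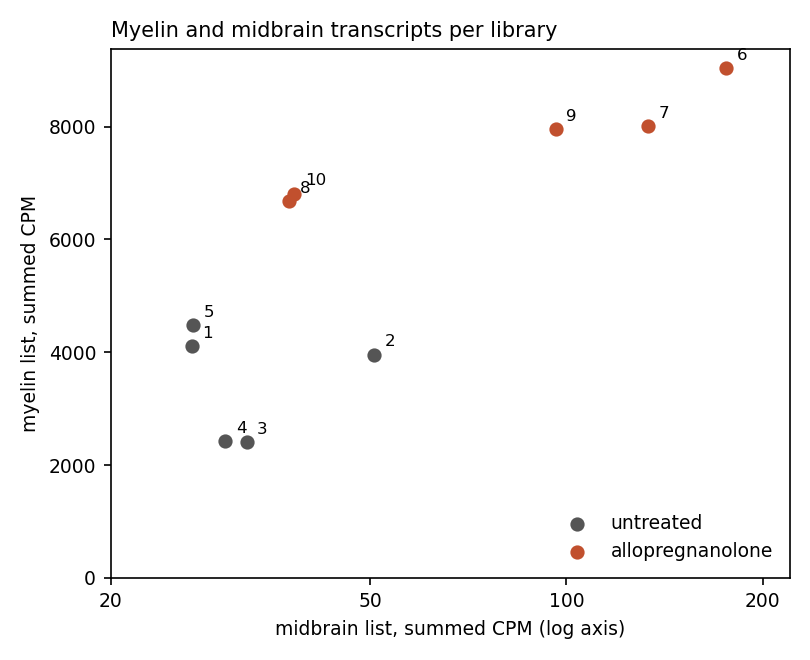
Summed CPM of the 18 myelin genes (vertical axis) against summed CPM of the 18 midbrain genes (horizontal, log axis) in each library, labelled by pup number. Treated libraries (6680 to 9040 CPM) lie above untreated ones (2401 to 4479 CPM) in myelin transcripts, at midbrain sums of 37.6 to 176 CPM.

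The groups separated as a whole. The mean Euclidean distance over all genes on the log2 CPM scale was 72.8 between and 64.4 within groups, and the real grouping gave the largest difference of all 126 splits (one-sided exact permutation p = 0.00794, the smallest possible). The first principal component held 25.3% of the variance and placed treated libraries at 17.9 to 30.1 and untreated ones at -33.8 to -1.01, with untreated library 5 nearest to the treated group. In exact two-sided permutation tests of each list's mean log2 CPM per library, 16 of 43 lists had an unadjusted p under 0.05 and none passed after adjustment (smallest adjusted p = 0.0683). That adjusted p belongs also to lists at the smallest possible exact permutation p, such as myelin. The small number of libraries thus limits what could pass after adjustment, and the lack of passes is no evidence against a difference. For myelin the mean was 5.92 ± 0.41 untreated and 6.99 ± 0.16 treated (SD, n = 5 each, exact permutation p = 0.00794, the smallest possible, higher in 5 of 5 libraries), and for glucocorticoid-responsive genes 3.43 ± 0.03 and 4.22 ± 0.29. By fry, which asks whether a list moves on balance without comparing it with other genes, 11 lists passed, 9 of them among the 15 that camera called. The oxidative stress and progestin receptor lists passed fry (adjusted p = 0.0380 each) but not camera. Lists that camera called but fry did not were inflammatory genes (fry adjusted p = 0.128), complement (0.140), general neurons (0.249), nuclear oxidative phosphorylation (0.159), red blood cells (0.133) and hypothalamus (0.155).

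The names of untreated libraries 1 to 3 carry another prefix than those of all other libraries, so a batch of that kind would hold untreated pups only. Within the other 7 libraries 99 genes passed, 76 higher and 23 lower. There 11 of the 18 myelin genes and 3 of the 16 glucocorticoid-responsive genes rose, with medians of 1.14 and 0.72 on the log2 scale, and none of the proliferation, inflammatory or complement genes passed edgeR's threshold (13, 4 and 4 lower at an unadjusted p under 0.05), with medians of -0.51, -0.10 and -0.24, against -0.56, -0.29 and -0.33 in all 10 libraries. Nor did any gene of GABA synthesis, of ribosomal proteins or of oligodendrocyte precursors in edgeR's test (3 higher, 8 lower and 6 higher at an unadjusted p under 0.05), nor of endothelium or general neurons (4 higher, and 7 higher and 3 lower). Of the astrocyte genes 3 rose and of the immature neuron genes 2 fell. The 3 untreated libraries of the other prefix differed from untreated libraries 4 and 5 in 1 gene past edgeR's threshold, with 366 at an unadjusted p under 0.05. Without untreated library 1, 3 or 4 the number of genes past the threshold was 1225, 1122 or 1086.

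Several list counts changed when 1 library was left out or with a covariate. The red blood cell and midbrain means had correlations of 0.66 and 0.70 with the groups. With such a covariate a lower count need not mean a smaller difference. With any 1 library left out the median log2 fold change of GABA synthesis was 0.14 to 0.17 (0.15 with all). That of proliferation was -0.64 to -0.45 (-0.56 with all). With the midbrain covariate these 2 medians were 0.08 and -0.55, and with the red blood cell covariate 0.19 and -0.48. The 9 lower proliferation genes became 4 without untreated library 1 and 3 without untreated library 4, and the 11 higher glucocorticoid-responsive genes became 7 without untreated library 4. The 3 lower complement genes became 1 without untreated library 4, treated library 7 or treated library 10, and 5 without untreated library 5. The 5 higher genes of GABA synthesis became 2 without untreated library 3 or 4, and 3 without untreated library 2 or treated library 6, 9 or 10. The 6 lower ribosomal protein genes became 3 without untreated library 1 or 4 or treated library 7 or 8, and 14 without untreated library 5. The 5 higher neuron genes became 2 without untreated library 1, 3 or 4 or treated library 7 or 10, 3 without treated library 8, and 8 without untreated library 2 or 5. With the red blood cell covariate the counts were 1 for proliferation, 3 for ribosomal proteins, and 0 for complement and GABA synthesis in edgeR's test (5 lower and 6 higher at an unadjusted p under 0.05). With the midbrain covariate they were 0 in edgeR's test for all of these 4 lists (8, 5 and 3 lower and 2 higher at an unadjusted p under 0.05). With it 4 astrocyte, 1 precursor and 1 endothelial gene rose and 1 immature neuron gene fell. Of the general neuron genes 0 rose and 2 fell with the midbrain covariate in edgeR's test (3 higher and 2 lower at an unadjusted p under 0.05). With the red blood cell covariate 2 general neuron genes rose and 2 fell, and 2 endothelial genes rose. The 4 lower inflammatory cytokine and chemokine genes became 2 with the red blood cell and 1 with the midbrain covariate. With library totals alone 13 ribosomal protein genes were lower. Among the lists that did not pass camera, the 6 higher oxidative stress genes became 3 without untreated library 3 or treated library 8 or 9. The 2 lower reactive astrocyte genes became 1 without untreated library 3 or 4 or treated library 7, 8 or 9, and 7 without untreated library 5. The 2 lower activated microglia genes became 1 without untreated library 1 or 4 or treated library 7, and 5 without untreated library 5. The 3 higher glutamate receptor genes became 1 without untreated library 1, 3 or 4 or treated library 8, 9 or 10.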

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

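The values in this part come from 256 groups of 5 values each, of which 11 held 1 value far from the other 4 by Dixon's test, and chance alone picks out about 1 in 20 such groups. The test was planned before the data were examined. Treated library 6 had 34.3 M counts in total, against 18.7 M to 21.8 M in the other treated libraries. The mean log2 CPM of the general neuron list was 9.50 in treated library 7 and 9.34 to 9.38 in the other treated libraries. Slc6a3, the dopamine transporter, was at 2.65 log2 CPM in untreated library 2 and at -1.03 to -0.35 in the other untreated libraries. Tmem52 was at 0.080 log2 CPM and Gabrd at 3.85 in treated library 6, against 0.83 to 1.13 and 4.50 to 4.73 in the other treated libraries. C4b was at 3.12 and Fgfr3 at 6.57 in treated library 7, against 3.56 to 3.73 and 6.70 to 6.74. Pvalb was at 3.71 in treated library 8, against 4.33 to 4.54, and Neu4 at 4.63 in treated library 9, against 4.22 to 4.28. Hmox1 was at 3.44 log2 CPM in untreated library 1, against 2.79 to 2.96 in the other untreated libraries. S100a10 was at 2.87 in untreated library 5, against 3.46 to 3.60.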

How the results depend on the processing

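The covariates of midbrain and myelin genes, library totals alone, the removal of GC and length trends, thinning, limma-trend with a prior count of 1 and leaving out untreated library 5 with treated library 6 were chosen after the gene test was seen. Of the 3160 values that 103 named genes past the threshold took in the alternatives, 2602 kept their direction and side of the threshold, 548 missed the threshold and 10 were opposite, all of the latter with the myelin covariate, which had a correlation of 0.89 with the groups. Of 495 values of the 15 lists, 407 were kept, 84 missed the threshold and 4 were opposite. Of the 17 lower inflammatory genes 17 passed with all libraries thinned to the smallest, 2 with a filter of 100 counts, which removes genes of low counts, 4 with the red blood cell covariate, 1 with the midbrain covariate and 0 with the myelin covariate in edgeR (956 of all genes at an unadjusted p under 0.05). Their number was 11 without untreated library 1, 9 without untreated library 4, 9 without treated library 7 and 10 without treated library 10.

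The number of genes past the threshold, 1926 (1131 higher, 795 lower), became 709 (463 and 246) with the red blood cell covariate, 233 (156 and 77) with the midbrain covariate and 99 (76 and 23) without the 3 libraries of the other prefix, which leaves 7 libraries. With the myelin covariate it was 0 (0 higher, 0 lower) in edgeR, with 956 genes at an unadjusted p under 0.05. With library totals alone 1451 genes were lower. With 1 library left out the total ran from 1086 to 2341, the higher genes from 647 to 1357 and the lower from 437 to 984. The counts were 1225 (712 and 513) without untreated library 1, 1122 (647 and 475) without 3 and 1086 (649 and 437) without 4. The number of lists past camera's threshold, 15, became 0 with an estimated correlation (3 at an unadjusted p under 0.05; fry 11), 30 with the mixed test of fry, 9 with the filter of 100 counts, 9 without the 3 libraries of the other prefix and 8 with the myelin covariate, and 11 to 17 with 1 library left out. The number of list means past the adjusted exact permutation threshold, 0 of 43 with 16 at an unadjusted p under 0.05, became 10 without untreated library 5 (0 to 10 with 1 library left out) and 7 with GC and length trends removed. The difference between and within groups, 8.42, stayed between 7.10 and 11.1 in the alternatives for which it was run over all genes. Over the 500 most variable genes alone it was 4.92, which is not on the same scale, since distance grows with the number of genes. The cause was not tested.

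Some values turned to the opposite direction. Gabra4, at 0.00, was -0.0062 with limma-trend at a prior count of 0.1, -0.0062 at 1 and -0.0062 at 4, -0.0023 with no filter, -0.0060 with the filter of 100, -0.0157 with upper-quartile and -0.0241 with quantile scaling, -0.0596 with library totals alone, -0.0141 after thinning and -0.0169 without the 3 libraries of the other prefix. With 1 library left out it was -0.0077 (untreated 1), -0.0378 (3), -0.0157 (5), -0.0554 (treated 7), -0.0459 (9) and -0.0084 (10), and the highest value was 0.0679 (treated 6). The GABA-A receptor list, not past the threshold, turned with an adjusted p (camera of limma) of 0.786 with the red blood cell, 0.653 with the midbrain and 0.892 with the myelin covariate, 0.408 with GC and length trends removed, 0.968 without untreated library 5, 0.962 without treated library 6, 0.948 without treated library 9 (0.560 at the lowest, without treated library 10, where it did not turn) and 0.794 without untreated 5 and treated 6. The red blood cell list had 0.733 with its own covariate. With the myelin covariate En1 was -1.25, Slc6a3 -0.59, Pax7 -1.01, Gata3 -1.17, Gabra2 0.070, Gabrd -0.072, Tspo 0.17, Abat -0.067, Uqcrc1 -0.047, Rpl13 0.040, Dlx1 0.31, Olig1 -0.045 and Gpr17 -0.13 on the log2 scale, and the general neuron, myelin and precursor lists had an adjusted p of 0.684, 0.888 and 0.735. The cause was not tested.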

Other observations

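The tests with the midbrain list, the lists of genes that fall or rise after birth, the myelin covariate, thinning and the GC and length trend were chosen after the gene test was seen, and the tests of microglial number, of slopes within groups and of single untreated libraries on the inflammatory and complement lists were written after the values were seen. The last one was run with 3 criteria in turn, each set after earlier values had been seen: on the median of the genes the explanation was argued against, on their upper quartile the test was void, since it failed with all libraries in, and the criterion given below is the difference over libraries. Genes that fall in the brain after birth were lower in the treated pups in 11 of 18 cases, with 1 higher. Among them were Igf2bp3, an RNA-binding protein of early development, at a log2 fold change of -1.60 (SE 0.40, n = 5 each), the early tubulin Tubb2b at -0.69 (SE 0.09), Mex3a at -0.72 (SE 0.16) and Gap43, a growth cone protein, at -0.37 (SE 0.06), while the imprinted gene Dlk1 was higher at 1.77 (SE 0.37). Genes that rise after birth were higher in 8 of 14 cases and lower in none. The synaptic vesicle genes Syt2 (0.88, SE 0.20) and Vamp1 (0.94, SE 0.19) and the potassium channels Kcna2 (0.41, SE 0.08) and Kcnc1 (0.42, SE 0.08) were among those past edgeR's threshold. With transcripts of X inactivation and hardly any Y-linked ones, untreated pup 2 (X inactivation genes 419 and Y-linked genes 0.0862 CPM) and treated pup 10 (491 and 0.863 CPM) stood apart from the other 8, whose Y-linked genes summed to 80.3 to 105 CPM.

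Lists not yet described did not pass camera's threshold. Interferon-stimulated genes had an adjusted p of 0.658 (1 of 24 lower), the unfolded protein response 0.658 (1 of 22 higher), cholesterol synthesis 0.316 (4 of 24 higher, 2 lower), neurotrophic factors 0.762 (1 higher and 1 lower of 18) and mitochondrially encoded mRNAs 0.0736 (0 of 13). Monocytes and perivascular macrophages had 0.857 (1 of 9 higher), pericytes 0.591 (0 of 10), meningeal fibroblasts 0.591 (0 of 13), choroid plexus 0.233 (1 of 15 higher) and ependymal cells 0.860 (0 of 12). The striatum had 0.129 (0 of 12), cerebral cortex 0.418 (1 of 12 lower), hippocampus 0.206 (2 of 10 higher), thalamus 0.145 (1 of 10 higher), cerebellum 0.526 (2 of 9 higher) and olfactory bulb 0.554 (1 higher and 1 lower of 8), all by camera of limma. With 1 library left out the cholesterol synthesis counts ran from 1 to 4 higher and from 0 to 3 lower in edgeR's test, the former at 1 without untreated library 1, 3 or 4 or treated library 7, 8 or 9. In the same settings the higher genes ran from 0 to 2 for hippocampus and from 1 to 2 for cerebellum, and the lower ones from 0 to 3 for olfactory bulb. The olfactory bulb median was -0.99 on the log2 scale. Its list mean was 4.21 and 4.35 log2 CPM in untreated libraries 3 and 4 and 2.36 to 3.07 in all others. Its sums did not set these libraries apart (850 and 787 against 743 to 895 CPM). These libraries had the lowest myelin sums (2401 and 2420 CPM, other untreated libraries 3958 to 4479 CPM). Their immature neuron means were the highest (5.27 and 4.93 log2 CPM). Whether those lists differ through olfactory bulb content was not tested. Meningeal genes summed to 643 CPM in treated library 6 and to 245 to 306 CPM in the others, and choroid plexus genes to 121 CPM in untreated library 2 and to 378 to 980 CPM in the others. Hindbrain and spinal cord genes summed to 0.178 to 0.277 CPM in untreated libraries to 4.41 and 2.76 CPM in treated libraries 6 and 7 and to 0.231 to 0.527 CPM in the other treated libraries.

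The higher myelin genes have technical and biological candidate explanations. GC or length trends were argued against, since the median log2 fold change of 1.16 was 1.19 with the trends removed (17 of 18 genes past the threshold). With all libraries thinned to the smallest the median was 1.17 (18 of 18 genes past the threshold). Random thinning keeps the expected ratios between libraries, so for genes of high counts this could hardly come out otherwise and does not test depth. A larger share of midbrain as the whole cause was weighed by the slope of the myelin mean on the midbrain mean within groups. It was 0.23 (upper 95% limit 0.70) where 1.14 would be needed. Without untreated library 2, whose midbrain sum was the highest untreated one, it was 0.20 (0.75) where 1.07 would be needed. Noise in the midbrain mean, which holds genes of low counts, pulls such a slope towards 0, so the slope cannot decide. Treated libraries 8 and 10 had lower midbrain sums (37.6 and 38.2 CPM) than untreated library 2 (50.7 CPM). Their myelin sums were higher (6680 and 6814 against 3958 CPM), which goes against midbrain share as the whole cause in these libraries. A part through midbrain share stays open: with the midbrain mean as covariate, whose correlation with the groups was 0.70, the median was 0.90 and 5 of 18 genes passed. A later developmental stage of the treated brains may account for the pattern, since genes that fall after birth had a median of -0.34 (15 of 18 below 0) and those that rise after birth 0.37 (13 of 14 above 0). A real age difference, a litter difference and a treatment that relieved a delay caused by the injury cannot be told apart here, as all follow the groups. Whether the genes that fall or rise after birth differ through a larger share of midbrain or hindbrain in some treated libraries was not tested.

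The lower inflammatory genes, 17 with a median log2 fold change of -2.50, were weighed against 2 explanations. A smaller number of microglia was not settled as a cause. The homeostatic microglia list had a median of -0.0040 with a lower quartile of -0.17. The 17 genes were chosen for being lower in these libraries, so their median is no fair measure to set this against. The 28 genes of the inflammatory and complement lists, fixed before, had a median of -0.30, nearer to that quartile. A change in number stays open. Members of the homeostatic list ran from -0.70 (Aif1) to 1.17 (Slc2a5), and transcripts do not count cells. Whether a single untreated library was the whole cause of the fall in the inflammatory and complement lists was not settled. The difference in the mean of their 28 genes per library was -0.44 log2 CPM, and -0.33 or further from 0 with any 1 untreated library left out. The upper 95% limit nearest 0 was -0.0082 (without untreated library 4). This criterion was the last of those tried, each set after earlier values had been seen, so no conclusion is drawn from it. For the 17 genes, chosen for being lower in these libraries, the median of -1.75 without untreated library 1 tests nothing. Within the 7 libraries of 1 prefix the median was -1.48 and 0 of 17 passed edgeR's threshold, and the 3 untreated libraries of the other prefix differed from the remaining 2 in 1 gene (366 at an unadjusted p under 0.05), so a part that follows the prefix is neither shown nor excluded. A weaker inflammatory state with allopregnanolone and a milder injury in those pups stay open and were not tested apart.

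The higher glucocorticoid-responsive genes, with a median log2 fold change of 0.68, were weighed against oligodendrocyte content and a single library. The latter was argued against, since the median was at least 0.58 with any 1 library left out. Oligodendrocyte content was argued against as the whole cause: among untreated libraries the myelin mean ran from 5.46 to 6.31 and the glucocorticoid mean from 3.40 to 3.47 log2 CPM, treated library 6 had the highest myelin mean (7.24) and the lowest treated glucocorticoid mean (3.90), and the slope within groups was -0.15 (upper 95% limit 0.35) where 0.57 would be needed. Without treated library 6 the slope was -0.03 (upper 95% limit 0.44) where 0.68 would be needed. The slope criterion was set after the values had been seen, which weakens it. A part stays open, since with the myelin mean as covariate, whose correlation with the groups was 0.89, the median was 1.06 but 0 of the 16 genes passed in edgeR's test (956 of all genes at an unadjusted p under 0.05). The treatment itself, the difference that the groups name, stays open and untested.

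Chance was tested with 100 of the 126 splits of the 10 libraries into 5 and 5. For the genes it was argued against: 1 of the 100 splits, the real one, gave as many as 1926 genes, and the highest of the others gave 12. The other splits mix treated and untreated libraries, which widens the spread within their groups and lowers their counts. Any other difference that follows the groups, such as litter or name prefix, could give the same result. For the number of gene lists chance cannot be excluded: 18 of the 100 splits gave as many as 15 lists past camera's threshold with the preset correlation, and the highest of the others gave 19.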
